A study of Homo sapiens with 15 samples.

How the data were processed

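RNA sequencing of SW480 cells was analysed in 12 libraries in 4 groups of 3, as assigned from the labels: control (wild-type cells exposed to PBS), LPS (1 µg/ml for 4 h), PINT shRNA1 (a lentiviral short hairpin against PINT) and PINT shRNA1 with LPS. The values are FPKM per Ensembl gene, computed by the authors and used as deposited. The submitters' processing notes name fastp, HISAT2 2.1.0, StringTie 1.3.4d and the GRCh37/hg19 build, without saying what each did. The labels list 15 samples, because each of the 3 RNA numbers of PINT shRNA1 has 2 samples, but the table holds 1 column for each RNA number, and whether a column holds 1 of the 2 samples or both is not recorded. Another 6 columns of the table were not used here. The labels do not say whether the replicates are separate cultures, so p-values measure only the spread between these libraries. The labels name no group with a non-targeting hairpin. The reference annotation at hand (GENCODE 29) is of another genome build and served only to mark genes that overlap others.

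Absolute depth cannot be recovered from FPKM. Depth relative to control replicate 1 was taken from the most frequent ratio of low values (0.01 to 0.3 FPKM) between libraries, and ratios between other pairs of libraries met those through control replicate 1 within 6.73e-05 (log2). FPKM summed to 409248 to 421487 for a library, and counting error cannot be given for a gene, so the precision stated is the SE of the fit. Of 57905 genes, 17214 with at least 0.5 FPKM in at least 3 of the 12 libraries were tested. Of a symbol listed more than once (2023 entries repeat a symbol already listed), the most abundant entry represented it in gene lists, while named genes were chosen by Ensembl gene.

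Values were analysed as log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3: 1 group-means fit of all 12 libraries, moderated with an intensity trend, two-sided contrasts, and Benjamini-Hochberg adjustment over all genes of a contrast. A gene was called at an adjusted p under 0.05. The contrasts were LPS against control, PINT shRNA1 against control, PINT shRNA1 with LPS against LPS, PINT shRNA1 with LPS against PINT shRNA1, and the interaction, which is the difference of the LPS responses. Because the targeted gene goes against the labels, PINT shRNA1 is used only as the name of the labelled libraries. LINC-PINT was also given an exact permutation test of 3 against 3 libraries.

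Gene lists, 25 in number, were tested in every contrast with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists of the contrast, with an estimated correlation and fry beside it. They were the PINT locus, components of Polycomb repressive complex 2, the LPS receptor and its adaptors, NF-kB subunits, kinases and inhibitors, inflammatory cytokines and chemokines, other NF-kB target genes, interferon-stimulated genes, immediate-early genes, p53 target genes, G2/M genes, DNA replication and E2F genes, replication-dependent histones, cholesterol and sterol synthesis, the unfolded protein and integrated stress responses, heat shock proteins, hypoxia and glycolysis, cytosolic ribosomal proteins, nuclear respiratory chain genes, mitochondrially encoded genes, Wnt target genes, intestinal epithelial differentiation, epithelial-mesenchymal transition and invasion, short hairpin processing and double-stranded RNA sensing, leukocyte markers, and fibroblast and endothelial markers. Members called were counted after adjustment over all genes and, beside that, over the list alone.

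Genes are named by a rule: for each contrast, the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 1 FPKM in the higher group and groups that do not overlap (a condition not applied to the interaction), leaving out clone-based names and small RNA; LINC-PINT and MKLN1 in every contrast; and up to 4 members with the smallest p of each list discussed. EZH2, RELA and TLR4 are named beyond it where the text says so, a choice made after their values were seen. A few genes that the rule names are not reported. The groups, contrasts, tests, gene lists, naming rule and the alternatives below, unless said, were fixed before the data were examined. The alternatives were median scaling, quantile normalization, rescaling to a common total, pseudocounts of 0.1 and 1, no filter and a filter of 1 FPKM, no intensity trend, robust moderation, a term for the replicate number, a fit of only the groups compared, a log2 threshold of 1 and leaving out each library. Library weights per group and a fit without genes that differ over 2-fold within a group were added after the data were seen.

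The pipeline was tested on simulated data of 17214 genes with 200 changed genes. Noise was independent and normal, with the same SD of a gene in all groups, and changed genes were drawn from the more abundant ones. The real groups differ in spread, so the rates below need not hold for the data. It recovered 70%, 86% and 98.5% of genes changed 1.5-, 2- and 4-fold in LPS against control, with 9, 12 and 15 false calls, and 39.5%, 72% and 95% in the interaction, with 6, 4 and 12. For PINT shRNA1 with LPS against LPS it recovered 67.5%, 87% and 98%, with 6, 9 and 16 false calls, and in the 2 contrasts simulated without change limma made 0 calls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.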

Results

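RNA sequencing of SW480 cells, a human colorectal cancer line that the labels describe as intestinal epithelial cells, was compared over a design of 2 factors. Per the labels, cells were either without a hairpin or carried a lentiviral short hairpin RNA directed at PINT, the long non-coding RNA whose gene is listed as LINC-PINT (ENSG00000231721), and were either left unstimulated or exposed to lipopolysaccharide (LPS) at 1 µg/ml for 4 h. The 4 groups of 3 libraries are called control, LPS, PINT shRNA1 and PINT shRNA1 with LPS. LPS is a component of the Gram-negative bacterial wall that is sensed through the receptor TLR4 and activates NF-kB, and the series title links PINT to p65, an NF-kB subunit, and to EZH2, the methyltransferase of Polycomb repressive complex 2. The deposited values are FPKM (fragments per kilobase of transcript, relative to the fragments mapped), so total read counts are unknown. Relative depth, recovered from the steps of the low values and set to 1 in control replicate 1, was 0.809 to 1 in control, 0.848 to 0.858 in LPS, 0.914 to 1.05 in PINT shRNA1 and 1.3 to 1.51 in PINT shRNA1 with LPS. Genes above 0 numbered 30725 to 31961 in the libraries labelled with the hairpin and 27078 to 28430 in the others. Pearson correlations of log2 values within a group were 0.982 to 0.991, and the median SD of a gene within a group was 0.128 (log2) in control and in LPS, 0.108 in PINT shRNA1 and 0.0868 in PINT shRNA1 with LPS. The first principal component, with 37.5% of the variance, separated the libraries labelled with the hairpin from those labelled without it, and the second, with 10.5%, separated the libraries exposed to LPS. Of 57905 listed genes, 17214 passed the low-value filter and were tested. Values below are mean FPKM ± SD over 3 libraries, and changes are log2 fold changes ± SE on the log2(FPKM + 0.5) scale, which understates the change of low genes.

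The targeted transcript was examined first. LINC-PINT was listed at 2.88, 2.56 and 2.51 FPKM in the 3 control libraries and at 2.4, 2.82 and 1.91 in the 3 LPS libraries. In the libraries labelled PINT shRNA1 it was at 4.55, 5.26 and 5.34, and in those labelled PINT shRNA1 with LPS at 3.54, 4 and 4.08. LINC-PINT was therefore higher, not lower, in every library labelled with the hairpin against it. Its log2 fold change was 0.81 ± 0.118 for PINT shRNA1 against control (limma, adjusted p = 0.000592) and 0.61 ± 0.118 for PINT shRNA1 with LPS against LPS (limma, adjusted p = 0.00284). A two-sided exact permutation test gave 0.1 for either contrast, the smallest p that groups of this size allow. These values are given for the gene as a whole and do not show which part the hairpin matches. Because the targeted gene goes against the labels, the groups, with and without the hairpin, are named below only by their labels, and no direction is to be read as an effect of less PINT. LINC-PINT was not called on LPS, at -0.14 ± 0.118 against control and -0.34 ± 0.118 against PINT shRNA1 (limma, adjusted p = 0.597 and 0.433), although it was lower in all 3 libraries of PINT shRNA1 with LPS than in those of PINT shRNA1. MKLN1, the gene next to LINC-PINT, was at 10.3 ± 2.42 in control, 8.80 ± 1.56 in LPS, 11.9 ± 0.876 in PINT shRNA1 and 12.3 ± 1.11 in PINT shRNA1 with LPS, and was not called in any contrast.

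**Figure D1:**
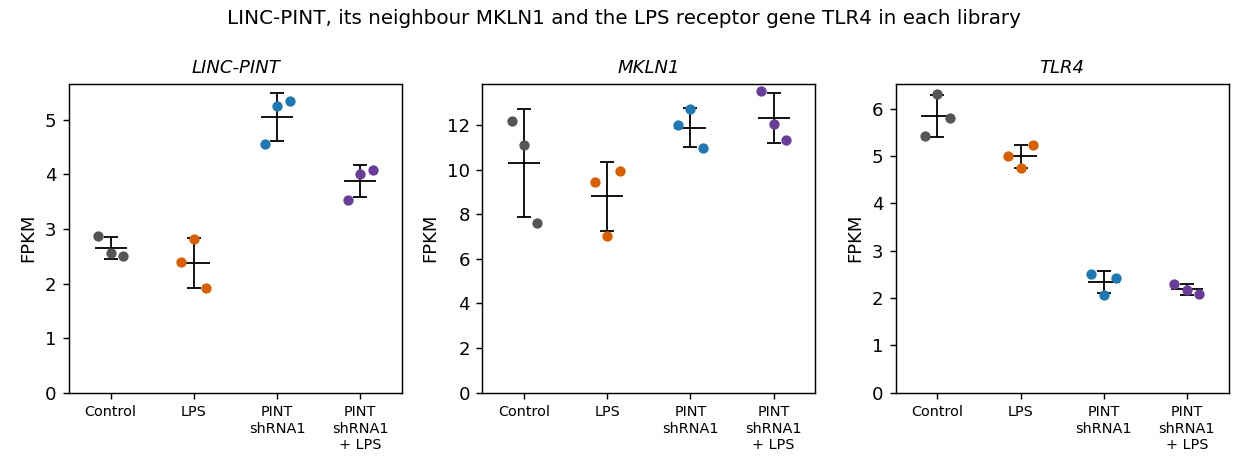
FPKM (vertical axis, starting at 0) of LINC-PINT, MKLN1 and TLR4 in each of the 12 libraries (points) by group, with the group mean (horizontal bar) and SD (whiskers). LINC-PINT lies at 1.91 to 2.88 in the 6 libraries labelled without the hairpin and at 3.54 to 5.34 in the 6 libraries labelled with the hairpin, and TLR4 lies lower in the latter.

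LPS against control asks which genes differ after 4 h of LPS in the libraries labelled without the hairpin. Chemokine and NF-kB-regulated genes led the response. CCL2, CCL7 and CCL20, chemokines for monocytes and lymphocytes, rose by 1.75 ± 0.066, 1.87 ± 0.092 and 1.70 ± 0.118, and CCL2 went from 17.8 ± 1.69 to 60.8 ± 1.33 FPKM. TNFAIP2, a TNF-induced gene, rose by 2.24 ± 0.202, the leukocyte adhesion molecule ICAM1 by 1.48 ± 0.054, and the inhibitor of apoptosis BIRC3 by 1.35 ± 0.115. SDC4, a cell-surface heparan sulfate proteoglycan, rose by 1.58 ± 0.031 from an already high level of 189 ± 3.13 to 565 ± 5.75 FPKM, and SGPP2, a sphingosine phosphate phosphatase, rose by 1.51 ± 0.037. The largest adjusted p among these 8 genes was 0.000161 (limma).

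Of the 22 tested inflammatory cytokines and chemokines, 12 rose (16 adjusted over the list alone), with a list median of 0.59 (camera with limma, adjusted p = 9.81e-25, and adjusted p = 0.00511 with an estimated correlation). Besides those above, CXCL1, a neutrophil chemokine, rose by 1.02 ± 0.051 and LTB, lymphotoxin beta, by 1.302 ± 0.067. Of 18 NF-kB subunits, kinases and inhibitors, 10 rose (10 adjusted over the list alone; median 0.53; camera adjusted p = 7.09e-15, and adjusted p = 0.000294 with an estimated correlation). They included the subunit genes NFKB1 (0.82 ± 0.06) and NFKB2 (0.84 ± 0.056) and the feedback inhibitors TNFAIP3 (0.84 ± 0.079) and TNIP1 (0.81 ± 0.062). Among 29 other NF-kB target genes, 11 rose and 1 fell (18 and 2 adjusted over the list alone; median 0.35; camera adjusted p = 2.51e-18, and adjusted p = 0.000182 with an estimated correlation). SAA2, an acute-phase protein gene, went from 78.9 ± 0.337 to 139 ± 3.37 FPKM (0.81 ± 0.048) and CD83, an immune surface protein gene, rose by 0.91 ± 0.073. Within the LPS receptor list, IRAK2, a kinase of the receptor's signalling complex, rose by 1.12 ± 0.088, while TLR4 itself was at -0.21 ± 0.085 (limma, adjusted p = 0.243), and the list was not called, with 2 of 13 higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.498). The lower member was CD14, at 0.618 ± 0.131 FPKM in control and 0.214 ± 0.0157 in LPS (-0.64 ± 0.139).

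Other lists moved less. Of 28 epithelial-mesenchymal transition and invasion genes, 6 rose (8 adjusted over the list alone; median 0.095; camera adjusted p = 4.23e-07, and adjusted p = 0.00768 with an estimated correlation). These included the plasminogen activator gene PLAU (1.22 ± 0.109). Among 22 Wnt target genes, 5 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.10; camera adjusted p = 0.00273, and adjusted p = 0.121 with an estimated correlation). NKD1, an inhibitor of Wnt signalling, fell by 0.38 ± 0.047, and DKK1, a secreted Wnt antagonist, was the member that rose (0.49 ± 0.067). The 34 genes of the G2/M list had a median of -0.10 (camera adjusted p = 0.00251, and adjusted p = 0.417 with an estimated correlation), with no member called lower (5 adjusted over the list alone), and UBE2C, the 1 member called, rose by 0.34 ± 0.064. Heat shock protein genes had a median of 0.048 (camera adjusted p = 0.0121, and adjusted p = 0.509 with an estimated correlation), with no member called by limma and 3 of 19 higher at an unadjusted p under 0.05. Of 38 interferon-stimulated genes 3 rose and 1 fell (3 and 2 adjusted over the list alone), without a call of the list (camera adjusted p = 0.286). The RNA sensor genes IFIH1 (0.46 ± 0.065) and DDX58 (0.54 ± 0.08) rose. Of 34 immediate-early genes 1 rose and 3 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.304). EGR1 and CTGF fell, at -0.51 ± 0.042 and -0.54 ± 0.069, and the ERK phosphatase gene DUSP5 rose by 0.42 ± 0.042. Of 32 hypoxia and glycolysis genes 3 fell (3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.304). The glucose transporter gene SLC2A3 (-0.22 ± 0.032), ANKRD37 (-0.52 ± 0.089) and NDRG1 (-0.34 ± 0.06) were the 3. EZH2, at 30.7 ± 0.985 in control and 29.4 ± 1.33 in LPS, was not called (-0.06 ± 0.045; limma, adjusted p = 0.543).

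The genes that fell most had no list in common. YTHDF2, a reader of N6-methyladenosine in RNA, fell by 1.83 ± 0.068 from 28.1 ± 0.707 to 7.58 ± 0.896 FPKM. KIAA1199, a hyaluronan-degrading factor, was at -0.86 ± 0.112, the scaffold protein gene DLG3 at -0.86 ± 0.135, and the small GTPase gene RASL11B at -0.71 ± 0.085. LINC01155 (-0.93 ± 0.159), CDK15 (-0.89 ± 0.196), HOXA11-AS (-0.72 ± 0.158) and the ribosomal pseudogene RPL39P (-1.04 ± 0.242) complete this group. The calls of CDK15, HOXA11-AS and RPL39P ended in 14, 16 and 20 of 26 alternative analyses.

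In all, limma called 475 of 17214 genes between LPS and control, 271 higher and 204 lower, and 41 of them changed by at least 1 on the log2 scale. With median scaling the split was 440 higher and 116 lower, and with quantile normalization 299 and 128. The number rests on the pooled spread of all 12 libraries: it was 127 when only the LPS and control libraries were fitted, 264 with library weights per group, 295 without control replicate 2 and 293 without LPS replicate 3.

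PINT shRNA1 against control asks what differs, without LPS, between libraries labelled with and without the hairpin. The difference was broad, and the labels name no group with a non-targeting hairpin, so the hairpin's target, the lentivirus and the selection of cells cannot be separated. A technical difference between the libraries cannot be separated from these either. PINT shRNA1 replicate 2 had 30898 genes above 0 at a relative depth of 0.914, against 28430 in control replicate 1 at a depth of 1. MMP9, a secreted gelatinase and listed NF-kB target, rose by 3.09 ± 0.091, from 0.769 ± 0.0357 to 10.4 ± 1.08 FPKM. SPRR2D, an epidermal envelope protein gene, rose by 3.12 ± 0.197, and the keratin-associated protein and keratin genes KRTAP3-1 and KRT37 rose by 2.11 ± 0.091 and 1.74 ± 0.122. The tight junction gene CLDN1 fell from 31.1 ± 1.44 to 8.40 ± 0.229 FPKM (-1.83 ± 0.047). PSAT1, an enzyme of serine synthesis, fell from 119 ± 1.76 to 40.8 ± 1.63 FPKM (-1.53 ± 0.046), and the aldehyde dehydrogenase gene ALDH3A1 (-1.53 ± 0.088), the YAP-regulated growth factor gene CTGF (-1.61 ± 0.069), SH3BGRL2 (-1.88 ± 0.063) and LRRC58 (-1.83 ± 0.046) fell as well. AKAP2 (-2.18 ± 0.404) and ATP6V0E2 (-1.60 ± 0.512) on the lower side, and ZNF8 (2.30 ± 0.473), KCTD20 (1.98 ± 0.402), TMEM189 (1.93 ± 0.453) and C19orf71 (1.99 ± 0.509) on the higher side, had SEs of 0.402 to 0.512, and a second gene listed as ZNF8 went the other way (-1.41 ± 0.370). The largest adjusted p among these 16 genes was 0.0394 (limma), and the call of ATP6V0E2 ended in 10 of 25 alternatives.

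Limma called 27.3% of all genes tested in this contrast, the share to set beside the member counts here and below. A count of called members near or below that share is no result about the list. Cholesterol and sterol synthesis genes were lower as a group. Of 25, 17 fell (17, with 1 higher, adjusted over the list alone), with a median of -0.41 (camera adjusted p = 8.96e-10, and adjusted p = 0.0825 with an estimated correlation). The enzymes CYP51A1 (-0.65 ± 0.05), MSMO1 (-0.78 ± 0.074), FDPS (-0.56 ± 0.058) and MVK (-0.83 ± 0.085) were among them. Of 8 intestinal epithelial differentiation genes 5 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.59; camera adjusted p = 2.04e-05, and adjusted p = 0.0661 with an estimated correlation). The brush border gene VIL1 went from 11.2 ± 0.152 to 4.21 ± 0.281 FPKM (-1.32 ± 0.068), the simple epithelial keratin genes KRT8 and KRT18 changed by -0.88 ± 0.076 and -0.82 ± 0.032, and EPCAM by -0.52 ± 0.045. CDX2 was the member that rose (0.38 ± 0.096). Most genes of this list, such as KRT20, MUC2 and FABP1, were below the low-value filter, so these values speak only for the 8 tested. In the list of the unfolded protein and integrated stress responses 13 of 33 fell and 7 rose (14 and 7 adjusted over the list alone; median -0.17; camera adjusted p = 0.00816, and adjusted p = 0.11 with an estimated correlation). SLC7A11, the cystine transporter gene, was at -1.32 ± 0.129, SHMT2, of mitochondrial serine metabolism, at -0.77 ± 0.072, and CHAC1, a glutathione-degrading enzyme gene, at -1.11 ± 0.149. Of 32 p53 target genes 8 fell and 3 rose (9 and 3 adjusted over the list alone; median -0.085; camera adjusted p = 0.0123, and adjusted p = 0.19 with an estimated correlation). DDB2 was at -0.46 ± 0.069 and C12orf5, also called TIGAR, at -0.35 ± 0.055, while the ribonucleotide reductase subunit gene RRM2B rose by 0.36 ± 0.062.

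Of 39 DNA replication and E2F genes 12 fell and 2 rose (13 and 3 adjusted over the list alone; median -0.075; camera adjusted p = 0.00068, and adjusted p = 0.171 with an estimated correlation). The lower members included GINS3 (-0.59 ± 0.057), CDC6 (-0.30 ± 0.042), CDT1 (-0.68 ± 0.102) and E2F2 (-0.70 ± 0.103). Of 34 G2/M genes 16 rose and 1 fell (17 and 1 adjusted over the list alone), by small amounts such as 0.20 ± 0.032 for TOP2A and 0.21 ± 0.034 for CDK1, and the list was not called (camera adjusted p = 0.0869). Of 13 mitochondrially encoded genes 7 fell and 2 rose (9 and 2 adjusted over the list alone; median -0.12; camera adjusted p = 0.00158, and adjusted p = 0.264 with an estimated correlation). MT-CO2 was at -0.38 ± 0.024 and MT-ND5 at -0.32 ± 0.029. All genes with a symbol starting with MT-, a wider set than these 13, held 24.8% to 25.9% of all FPKM in control and 22.9% to 23.7% in PINT shRNA1. With quantile normalization the median change of the 13 genes was 0, and MT-ND1, called higher at 0.27 ± 0.029, turned to -0.075. That method gives genes of the same rank the same value in every library, and these genes are among the most abundant. It therefore removes most of their change by construction and does not tell whether the change depends on scaling.

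NF-kB-related lists held changes in both directions. Of 29 other NF-kB target genes 9 fell and 4 rose (9 and 6 adjusted over the list alone; median -0.057; camera adjusted p = 0.0423, and adjusted p = 0.135 with an estimated correlation). Besides MMP9, which rose, SAA1 and SAA2 fell by 1.09 ± 0.050 and 1.36 ± 0.048, and the cyclin gene CCND1 went from 574 ± 6.73 to 319.7 ± 2.59 FPKM (-0.84 ± 0.024). Of 22 cytokines and chemokines 2 rose and 5 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.752). IL32 (0.76 ± 0.052) and TNFSF10, the gene of the death ligand TRAIL (1.26 ± 0.113), rose, and LIF (-0.41 ± 0.062) was among the lower. Of 18 NF-kB subunits, kinases and inhibitors 4 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.826). The kinase genes IKBKB (0.48 ± 0.064) and CHUK (0.25 ± 0.054) rose, and NFKB2 (-0.27 ± 0.056) and TNIP1 (-0.30 ± 0.062) fell. TLR4 was the 1 member of the LPS receptor list called among 13 tested (1 adjusted over the list alone; camera adjusted p = 0.16), going from 5.85 ± 0.445 to 2.33 ± 0.232 FPKM (-1.17 ± 0.085; limma, adjusted p = 5.47e-06). Of 38 interferon-stimulated genes 12 rose and 5 fell (13 and 5 adjusted over the list alone; camera adjusted p = 0.826). ISG15 was at 0.77 ± 0.1 and IFIH1 at -0.39 ± 0.065. Of 11 Polycomb repressive complex 2 components 2 rose (1 adjusted over the list alone; camera adjusted p = 0.854), among them JARID2, a cofactor of the complex, which went from 3.58 ± 0.316 to 7.40 ± 0.230 FPKM (0.96 ± 0.076). EZH2 was at 29.4 ± 0.515 FPKM and not called (-0.06 ± 0.045; limma, adjusted p = 0.349; named for its place in the series title, outside the rule). RELA, the gene of p65 and named for the same reason, rose from 13.0 ± 3.39 to 22.2 ± 1.24 FPKM (0.78 ± 0.224; limma, adjusted p = 0.0247). It was not called in the other contrasts, at 0.325 ± 0.224 for PINT shRNA1 with LPS against LPS (limma, adjusted p = 0.312).

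The remaining lists were not called in this contrast. Of 32 hypoxia and glycolysis genes 13 rose and 3 fell (13 and 3 adjusted over the list alone; camera adjusted p = 0.138). NDRG1 was at 0.64 ± 0.06 and P4HA1 at 0.64 ± 0.073, but SLC2A3 at -0.77 ± 0.032. Of 28 epithelial-mesenchymal transition and invasion genes 12 rose and 5 fell (13 and 7 adjusted over the list alone; camera adjusted p = 0.497). The integrin gene ITGA5 was at 0.59 ± 0.068 and ITGA3 at -0.63 ± 0.065. Of 34 immediate-early genes 4 rose and 7 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.0822). CYR61 was at -1.35 ± 0.05 and DUSP4 at -0.69 ± 0.06. Of 22 Wnt target genes 7 rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.932). AXIN2 (0.38 ± 0.033) and LEF1 (0.47 ± 0.044) rose, and SOX9 (-0.42 ± 0.029) fell. Of 15 genes that process short hairpin RNAs or sense foreign RNA 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.763). XPO5 (0.43 ± 0.046) and DROSHA (0.46 ± 0.091) rose. Camera adjusted p was 0.854 for heat shock proteins (5 of 19 rose and 4 fell), 0.077 for cytosolic ribosomal proteins (4 of 53 rose and 7 fell), 0.932 for nuclear respiratory chain genes (7 of 49 rose and 3 fell) and 0.497 for replication-dependent histones (1 of 20 rose and 1 fell). Adjusted over the list alone these counts were 9 and 5, 3 and 6, 7 and 3, and 1 and 1. The PINT locus list, with LINC-PINT the 1 of 2 members called (1 adjusted over the list alone), had camera adjusted p = 0.216. Markers of other cell types were not called as lists. Of 5 tested fibroblast and endothelial markers 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.11). COL6A3 rose by 1.35 ± 0.095. Of 5 tested leukocyte markers 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.984). CD68 was at 0.751 ± 0.0678 in control and 1.45 ± 0.129 in PINT shRNA1.

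In all, limma called 4693 genes between PINT shRNA1 and control, 2913 higher and 1780 lower, of which 240 changed by at least 1 on the log2 scale. The excess of higher genes depends on the scaling: the split was 2215 and 2151 with median scaling, 2263 and 2204 with quantile normalization, and 3233 and 1583 after rescaling to a common total.

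PINT shRNA1 with LPS against LPS asks how the cells differ once LPS has acted. Limma called 29.2% of all genes tested in this contrast, the share to set beside its member counts. Several chemokine genes that LPS had raised were lower in the libraries labelled PINT shRNA1 with LPS. CCL20 was at 37.1 ± 3.02 FPKM in LPS and 12.2 ± 1.31 in PINT shRNA1 with LPS (-1.56 ± 0.118), CCL2 at -0.92 ± 0.066 and CXCL1 at -0.85 ± 0.051, while IL32 was higher (0.53 ± 0.052). Of 22 cytokines and chemokines 12 fell and 3 rose (14 and 3 adjusted over the list alone; median -0.35; camera adjusted p = 4.33e-05, and adjusted p = 0.198 with an estimated correlation). Of 29 other NF-kB target genes 9 fell and 2 rose (10 and 3 adjusted over the list alone; median -0.17; camera adjusted p = 4.33e-05, and adjusted p = 0.0241 with an estimated correlation). SAA2 fell from 139 ± 3.37 to 34.8 ± 1.57 FPKM (-1.98 ± 0.048), SAA1 was at -1.48 ± 0.05 and CCND1 at -0.78 ± 0.024, and MMP9 rose by 2.88 ± 0.091. Of 18 NF-kB subunits, kinases and inhibitors 8 fell and 4 rose (10 and 4 adjusted over the list alone; median -0.31; camera adjusted p = 0.0407, and adjusted p = 0.168 with an estimated correlation). RELB was at -0.82 ± 0.127, NFKB2 at -0.63 ± 0.056, TNIP1 at -0.67 ± 0.062 and IKBKB at 0.44 ± 0.064. The LPS receptor list was lower (median -0.26; camera adjusted p = 0.0244, and adjusted p = 0.198 with an estimated correlation), with 4 of 13 lower and 2 higher (6 and 2 adjusted over the list alone). TLR4 was at 2.19 ± 0.110 FPKM against 4.99 ± 0.247 (-1.03 ± 0.085), IRAK2 at -0.64 ± 0.088 and IRAK4 at -0.58 ± 0.133. CD14, of the 2 higher members, went the other way at a low level, 0.590 ± 0.113 FPKM against 0.214 ± 0.0157 (0.61 ± 0.139).

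The 271 genes that LPS raised in the libraries labelled without the hairpin had a median of -0.313 in this contrast, with a bootstrap interval over genes of -0.385 to -0.263. The median was -0.53 over the genes called with only the groups compared in the fit, and -0.79 over those raised by at least 1 on the log2 scale. Of these genes 217 (80.1%) were lower in PINT shRNA1 with LPS, 170 passed the test as lower and 28 as higher. Both contrasts use the LPS libraries, which alone pulls such a median below 0: in 100 simulations with no difference by hairpin label, the 271 genes raised with the smallest p had a median of -0.016 (range -0.028 to -0.006), with 60.9% of genes lower. The simulations took the fitted means as true and called more genes than the data, a median of 742, whose median was -0.026 (range -0.035 to -0.018). When each LPS library in turn was left out of the selection and alone set against PINT shRNA1 with LPS, so that none was shared, the medians were -0.317, -0.317 and -0.347 over 208, 216 and 186 genes. This check was added after the data were seen. Without LPS, the same 271 genes had a median of 0.008 between PINT shRNA1 and control, and 69 were called lower and 72 higher.

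**Figure D2:**
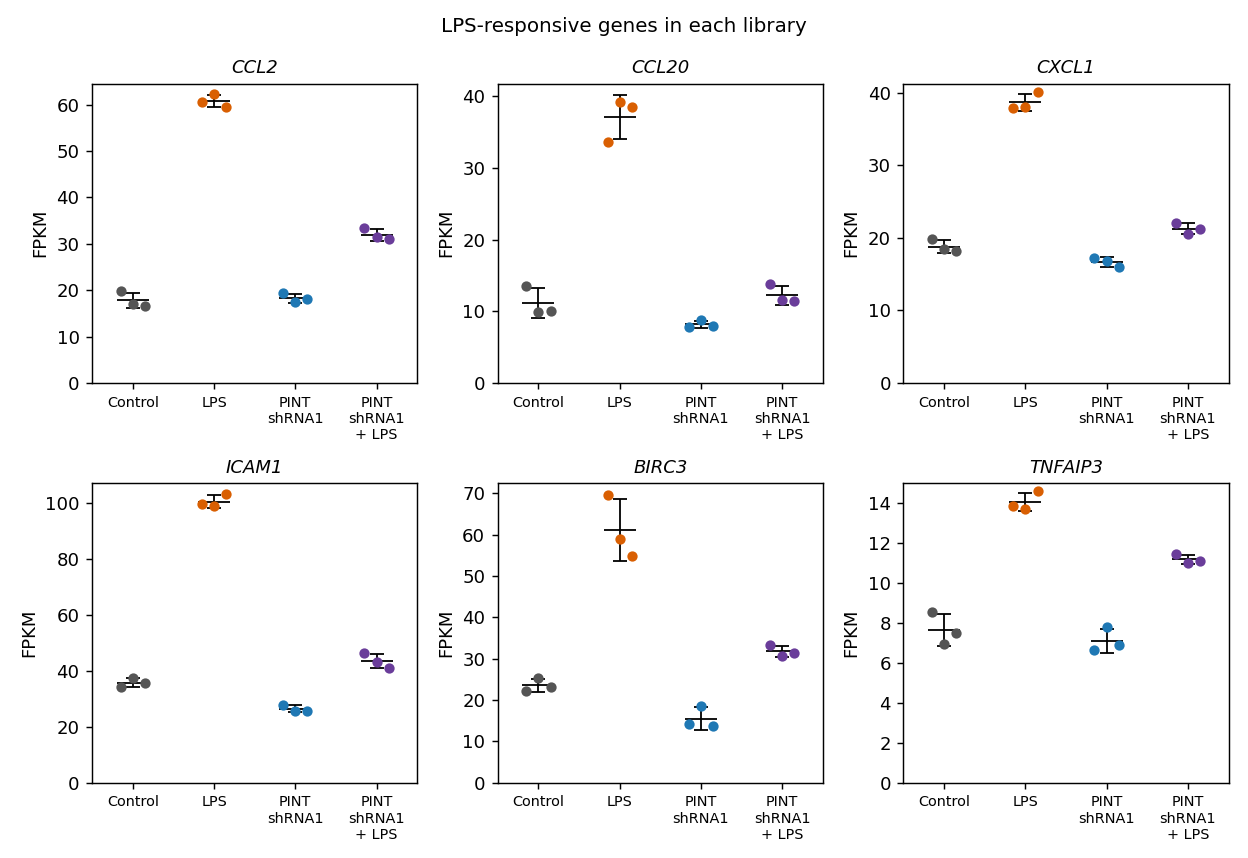
FPKM (vertical axes, starting at 0) of 6 LPS-responsive genes in each of the 12 libraries (points) by group, with the group mean (horizontal bar) and SD (whiskers). For CCL20 the mean is 11.2 in control, 37.1 in LPS, 8.18 in PINT shRNA1 and 12.2 in PINT shRNA1 with LPS, and in all 6 panels the LPS libraries lie highest.

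Lists outside inflammation differed as well. Cholesterol synthesis genes (17 of 25 lower, 17 with 2 higher adjusted over the list alone; median -0.47; camera adjusted p = 4.72e-10, and adjusted p = 0.051 with an estimated correlation) included MSMO1 (-0.92 ± 0.074) and HSD17B7 (-1.06 ± 0.102). Intestinal differentiation genes (5 of 8 lower and 1 higher, 7 and 1 adjusted over the list alone; median -0.54; camera adjusted p = 4.33e-05, and adjusted p = 0.044 with an estimated correlation) included VIL1 (-1.32 ± 0.068) and KRT19 (-0.36 ± 0.046). CDX2 was the higher member (0.62 ± 0.096). Of 32 p53 target genes 11 fell and 2 rose (11 and 2 adjusted over the list alone; median -0.14; camera adjusted p = 0.00426, and adjusted p = 0.168 with an estimated correlation). PLK2 was at -0.49 ± 0.071 and DDB2 at -0.39 ± 0.069. G2/M genes were higher (17 of 34, and 1 lower; 17 and 1 adjusted over the list alone; median 0.12; camera adjusted p = 0.00661, and adjusted p = 0.285 with an estimated correlation). The mitotic kinase gene AURKB was at 0.57 ± 0.069. DNA replication genes were lower (10 of 39, and 4 higher; 10 and 4 adjusted over the list alone; median -0.070; camera adjusted p = 0.00767, and adjusted p = 0.246 with an estimated correlation). GINS3 was at -0.56 ± 0.057. Hypoxia and glycolysis genes were higher (11 of 32, and 1 lower; 12 and 1 adjusted over the list alone; median 0.19; camera adjusted p = 0.0487, and adjusted p = 0.306 with an estimated correlation). EGLN3, an oxygen-sensing hydroxylase gene, was at 1.12 ± 0.151. Ribosomal protein genes (18 of 53 lower and 3 higher, 20 and 3 adjusted over the list alone; median -0.078; camera adjusted p = 4.33e-05, and adjusted p = 0.306 with an estimated correlation) and mitochondrially encoded genes (7 of 13 lower and 1 higher, 7 and 1 adjusted over the list alone; median -0.10; camera adjusted p = 0.00661, and adjusted p = 0.285 with an estimated correlation) shifted by small amounts, such as -0.25 ± 0.029 for RPS4X and -0.32 ± 0.024 for MT-CO2. JARID2 was again higher (1.00 ± 0.076), and EZH2 was not called (0.02; limma, adjusted p = 0.741; named outside the rule, and below 0 with median scaling and quantile normalization).

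Among single genes, SPRR2D (2.86 ± 0.197), KRTAP3-1 (2.24 ± 0.091) and ASMTL-AS1 (1.96 ± 0.173) were higher, and CLDN1 (-2.24 ± 0.047), IGFL1 (-2.01 ± 0.126) and LRRC58 (-1.80 ± 0.046) were lower. YTHDF2 was higher by 2.23 ± 0.068, since it was low in the LPS libraries, at 7.58 ± 0.896 FPKM. UPK3BL (2.34 ± 0.251) and DAG1 (-2.17 ± 0.465) are also of this group. MFSD2B (2.37 ± 0.742), TIGD1 (2.23 ± 0.716), IGF2 (-2.26 ± 0.687), FBXO34 (-2.15 ± 0.622) and HSPA2 (-2.08 ± 0.693) had calls that ended in 6 to 11 of 25 alternatives. In all, limma called 5033 genes, 3039 higher and 1994 lower, of which 288 changed by at least 1 on the log2 scale. The split was 2349 higher and 2530 lower with median scaling, 2561 and 2361 with quantile normalization, and 3370 and 1785 after rescaling to a common total.

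The differences seen with and without LPS were set against each other. Across the 17214 genes, which are not independent replicates, the log2 fold changes of the hairpin-labelled libraries with and without LPS correlated with Pearson r = 0.693 and Spearman rho = 0.689. The libraries of the contrasts are not shared. Among genes called in both, 2013 were higher in both, where independent lists would share 514, and 1314 were lower in both, against 206, while 12 went opposite ways.

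PINT shRNA1 with LPS against PINT shRNA1 asks for the LPS response in the libraries labelled with the hairpin. Several genes that LPS had raised without it rose here too. SDC4 rose by 0.74 ± 0.031, SGPP2 by 0.76 ± 0.037, CCL2 by 0.79 ± 0.066, ICAM1 by 0.71 ± 0.054, BIRC3 by 1.02 ± 0.115 and PLAU by 0.73 ± 0.109. EMP2, an epithelial membrane protein gene, went from 6.46 ± 0.456 to 14.0 ± 0.431 FPKM (1.06 ± 0.055), and UPK3BL from 0.682 ± 0.164 to 3.10 ± 0.713 (1.60 ± 0.251). TSFM, a mitochondrial translation factor gene, fell by 1.38 ± 0.165, and EDA by 0.84 ± 0.115. The largest adjusted p among these 10 genes was 0.0361 (limma), and the calls of UPK3BL, PLAU and EDA ended in 14 of 25, 9 of 26 and 7 of 26 alternatives.

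By list, 4 of 18 NF-kB subunits, kinases and inhibitors rose (7 adjusted over the list alone; median 0.24; camera adjusted p = 1.81e-11, and adjusted p = 0.000787 with an estimated correlation). They included NFKB2 (0.49 ± 0.056), TNFAIP3 (0.62 ± 0.079) and TNIP1 (0.45 ± 0.062). Of 22 cytokines and chemokines 3 rose, 8 with 1 lower adjusted over the list alone (median 0.20; camera adjusted p = 1.2e-14, and adjusted p = 0.0258 with an estimated correlation). LTB was at 0.56 ± 0.067, and IL23A was at 0.48 ± 0.083 (limma, adjusted p = 0.057). Of 29 other NF-kB target genes 3 rose (9 adjusted over the list alone; median 0.19; camera adjusted p = 8.31e-12, and adjusted p = 0.000787 with an estimated correlation). Of 28 invasion genes 2 rose (2 adjusted over the list alone; median 0.032; camera adjusted p = 0.000145, and adjusted p = 0.0317 with an estimated correlation). Interferon-stimulated, immediate-early and ribosomal protein genes had medians of 0.041, 0.033 and -0.054 (camera adjusted p = 0.000914, 0.0193 and 0.000195, and adjusted p = 0.135, 0.434 and 0.673 with an estimated correlation). In these 3 lists no member was called by limma, and at an unadjusted p under 0.05 the counts were 7 higher and 1 lower of 38, 5 and 3 of 34, and 1 and 13 of 53. TLR4 (-0.08 ± 0.085) and EZH2 (0.02), named outside the rule, were not called (limma, adjusted p = 0.847 and 0.915).

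In all, limma called 32 genes, 28 higher and 4 lower, of which 5 changed by at least 1 on the log2 scale. The count was 59 with median scaling, 57 with quantile normalization, 65 with library weights per group, 18 without the intensity trend, 19 without PINT shRNA1 replicate 1 and 20 without PINT shRNA1 replicate 2.

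The LPS responses in both backgrounds were then compared gene by gene. Of the 475 genes called in the libraries labelled without the hairpin, 428 (90.1%, Wilson interval 87.1 to 92.5) changed in the same direction in the libraries labelled PINT shRNA1. Over all 17214 genes tested the share was 59.4%. The interval treats genes as independent, which they are not. The 271 higher genes had a median of 0.50 in the libraries labelled without the hairpin and 0.18 in the others, and 22 of them were called there. The 204 lower genes had medians of -0.41 and -0.13, and none was called there by limma, with 83 lower at an unadjusted p under 0.05. Across the 475 genes, which pool both signs, the responses correlated with Pearson r = 0.724 and Spearman rho = 0.754. Within the 271 higher genes r was 0.472 (rho 0.518), and within the 204 lower genes 0.0141 (rho 0.239). Selection on the response without the hairpin inflates the first median of each pair. In the other direction, of the 28 genes called higher in the libraries labelled with the hairpin, 22 were called in the libraries labelled without the hairpin, and 20 had the larger response there (median 0.83 against 0.53).

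**Figure D3:**
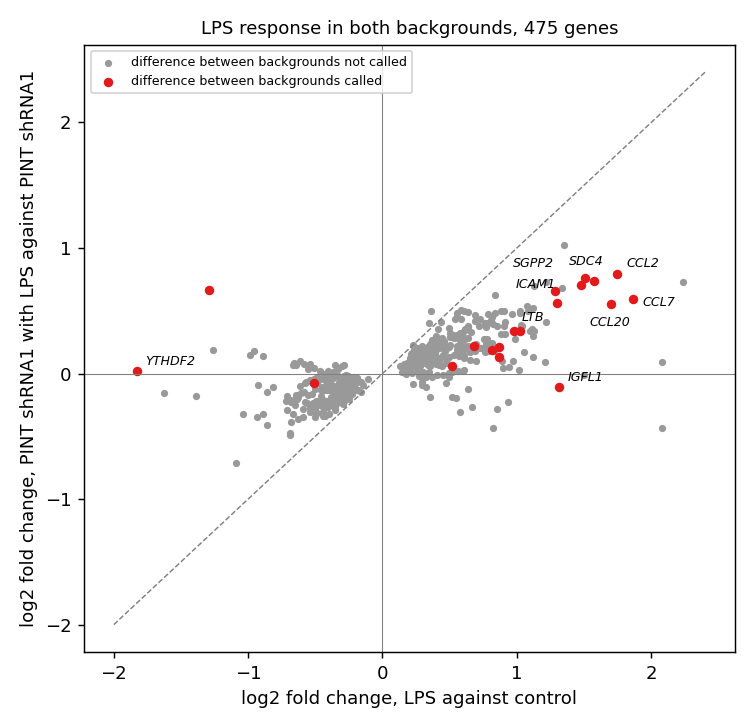
Log2 fold change on LPS in the libraries labelled without the hairpin (horizontal axis) and in the libraries labelled PINT shRNA1 (vertical axis) for the 475 genes called in the former, with equality as the dashed line and genes with a called difference between backgrounds in red. Most points lie on the side of 0 given by the libraries labelled without the hairpin but nearer to 0 on the vertical axis, as for SDC4 (1.58 and 0.74).

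The interaction tests the difference of the LPS responses itself. It was negative, a smaller rise in the libraries labelled PINT shRNA1, for the chemokine genes CCL7 (-1.27 ± 0.13), CCL20 (-1.15 ± 0.167), CCL2 (-0.96 ± 0.093) and CXCL1 (-0.68 ± 0.073), for LTB (-0.74 ± 0.095), ICAM1 (-0.77 ± 0.077), SDC4 (-0.84 ± 0.043), SGPP2 (-0.75 ± 0.053) and SAA2 (-0.63 ± 0.069). It was also negative for IGFL1 (-1.42 ± 0.179), at 1.31 without the hairpin label and -0.10 with it, the latter not called (limma, adjusted p = 0.862). CCL7 went from 3.64 ± 0.138 to 14.7 ± 1.33 FPKM in the libraries labelled without the hairpin and from 2.88 ± 0.389 to 4.59 ± 0.149 in the libraries labelled PINT shRNA1. The interaction was positive for YTHDF2 (1.85 ± 0.096), which fell only in the libraries labelled without the hairpin, at 36.8 ± 1.17 and 37.4 ± 0.521 FPKM in the others, for EMP2 (1.10 ± 0.078), for EGR1 (0.43 ± 0.06) and for UPK3BL (2.24 ± 0.355). The largest adjusted p among these 14 genes was 0.0493 (limma). The calls of UPK3BL, EGR1 and CCL20 ended in 15 of 24, 11 of 25 and 11 of 25 alternatives. LINC-PINT itself was at -0.20 ± 0.166 (limma, adjusted p = 0.817) and MKLN1 at 0.25 ± 0.236 (adjusted p = 0.838).

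Cytokines and chemokines had a median interaction of -0.40 (4 of 22 lower, 8 adjusted over the list alone; camera adjusted p = 1.68e-12, and adjusted p = 0.0404 with an estimated correlation). For NF-kB subunits, kinases and inhibitors it was -0.32 (camera adjusted p = 2.59e-06, and adjusted p = 0.00687 with an estimated correlation). No single one of these 18 genes was called by limma, and at an unadjusted p under 0.05 there were 7 lower and 1 higher, as there were adjusted over the list alone. NFKB1 was at -0.42 ± 0.085 and NFKBIA, the gene of the inhibitor IkB alpha, at -1.12 ± 0.272 (limma, adjusted p = 0.158 and 0.268). For other NF-kB target genes the median was -0.21 (2 of 29 lower, 7 adjusted over the list alone; camera adjusted p = 6.83e-07, and adjusted p = 0.00684 with an estimated correlation). Ribosomal protein, invasion and Wnt target genes had medians of -0.061, -0.079 and 0.12 (camera adjusted p = 0.000452, 0.0068 and 0.00254, and adjusted p = 0.637, 0.111 and 0.111 with an estimated correlation). In these 3 lists no member was called by limma, with 7 lower of 53, 3 lower of 28, and 7 higher and 1 lower of 22 at an unadjusted p under 0.05. In all, limma called 22 of 17214 genes, 6 with a higher and 16 with a lower interaction, and 8 of them differed by at least 1 on the log2 scale.

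**Figure D4:**
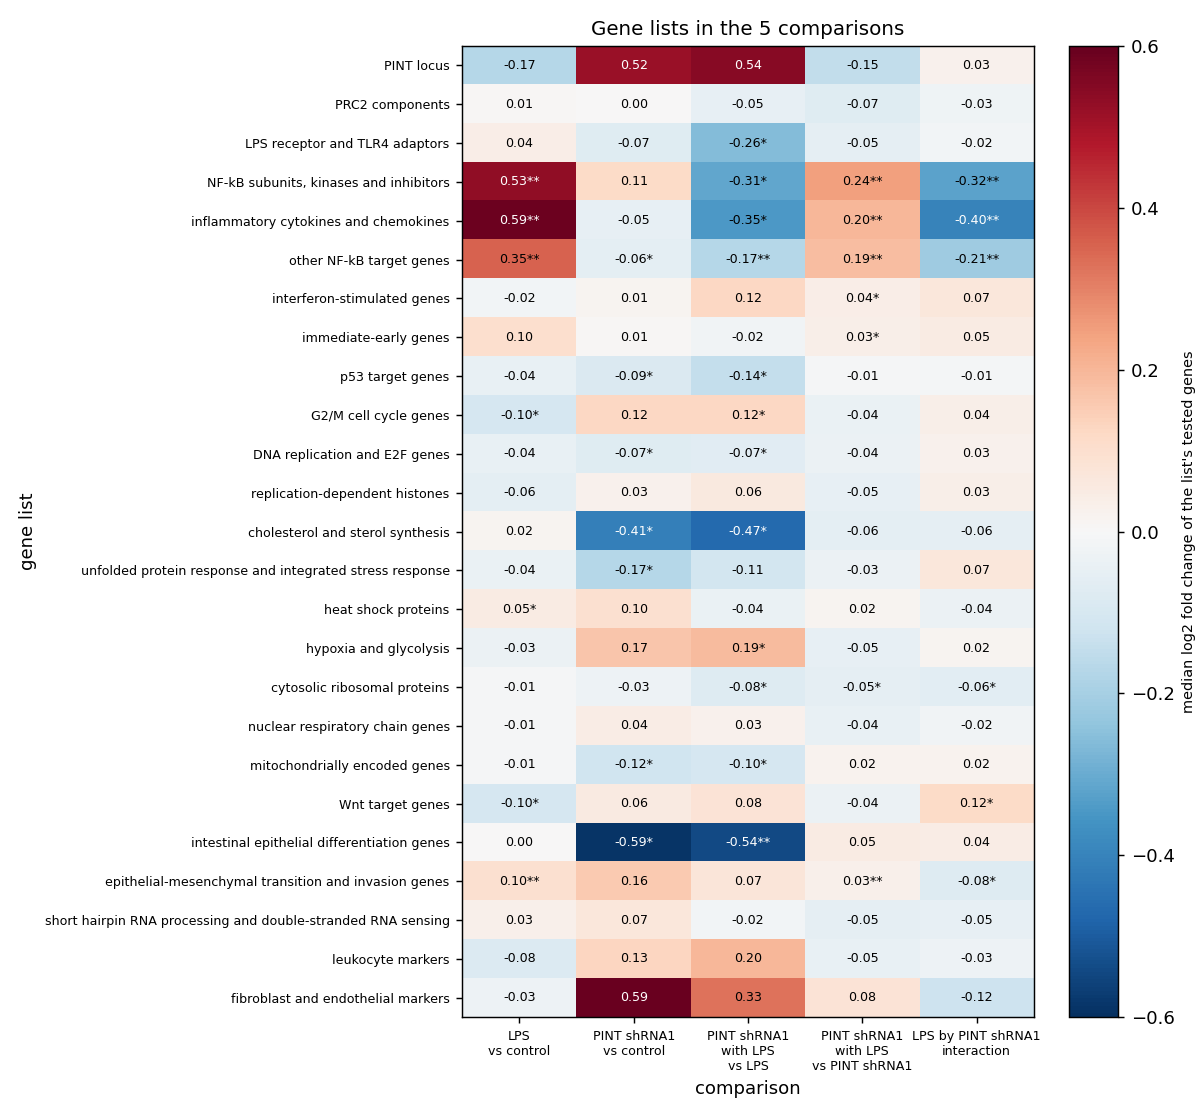
Median log2 fold change of the tested genes of each of 25 gene lists (rows) in 5 comparisons (columns), coloured from blue (lower) to red (higher). One asterisk marks a camera adjusted p under 0.05 with the preset correlation and a second asterisk one that also holds with an estimated correlation: the NF-kB lists and the cytokine list carry both in LPS against control (medians 0.35 to 0.59) and in the interaction (-0.40 to -0.21).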

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

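Of the tests in this part, those of the MKLN1 reads, of the residuals of the additive fit and of the called genes at a lower pseudocount were chosen after the result was seen.

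The LPS response differed between the backgrounds by the interaction test in 22 genes. The differences (log2) were 2.242 for UPK3BL, 1.852 for YTHDF2, 1.104 for EMP2, 0.434 for EGR1, -1.417 for IGFL1, -1.271 for CCL7, -1.149 for CCL20, -0.956 for CCL2, -0.841 for SDC4, -0.77 for ICAM1, -0.752 for SGPP2 and -0.743 for LTB. List medians were -0.321 for NF-kB subunits, kinases and inhibitors, -0.403 for inflammatory cytokines and chemokines and -0.215 for other NF-kB target genes. Of 100 splits that permute the hairpin labels within each LPS exposure, 6 gave at least as many calls as the real 22, the highest being 51. In the other 5 the LPS-exposed libraries stay apart by hairpin label while those without LPS are mixed, so the difference by label, 5033 calls with LPS, enters the interaction. By the rule written beforehand (at least 5 such splits) chance stays open, and these counts do not tell whether it can be excluded. When the residuals of a fit with hairpin and LPS effects were permuted instead, only the real order, 1 of 100, gave as many, with a highest other count of 2. That argues against chance but does not exclude it. The test was chosen after the result was seen, and it moves residuals between groups of unequal spread (median SD 0.128 in control and 0.0868 in PINT shRNA1 with LPS).

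The first pattern weighed is the smaller LPS response of inflammatory genes in the libraries labelled PINT shRNA1. Scaling is argued against, since with quantile normalization the cytokine and chemokine median was -0.393 against -0.403. Compression of low values by the pseudocount was tested on the 33 members of these 3 lists with at least 10 FPKM. Their median was -0.328 with a pseudocount of 0.1 (interval over genes -0.429 to -0.062) against -0.333. The pseudocount changes values little at such levels, so the closeness of these medians was given in advance. What they show is a smaller response in genes where compression is slight. The interval did not meet the limit set beforehand and lower members were not covered, so compression stays open for the lists as a whole. All 16 genes called lower in the interaction stayed called with that pseudocount. A weakening of the whole LPS response may be what is seen, rather than one of inflammatory genes alone, since genes lowered by LPS on average over both backgrounds had a median interaction of 0.134, also toward a smaller response. The libraries labelled without the hairpin varied more within a group (median SD 0.128 against 0.108 and 0.0868). In this selection that alone can pull the median toward a smaller response with the hairpin label, by an amount not measured. Lower TLR4, the lentivirus, cell selection, a technical difference between the libraries and PINT itself were not separated by this design.

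The second is LINC-PINT, higher in the libraries labelled with the hairpin against it. A shift of all genes of similar level is argued against, since genes within 2-fold of its level had a median of 0.052 without LPS and 0.063 with LPS. Its rise was not unique among these 4495 genes: it lay at percentile 97.5 without LPS and 92.8 with LPS. Reads of the neighbouring MKLN1 are argued against without LPS, where LINC-PINT changed by 0.593 ± 0.204 more than MKLN1, and stay open with LPS, where the difference was 0.141 ± 0.204. An exchange of labels between whole groups was not tested and stays open. No biological explanation was tested.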

How the results depend on the processing

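The library weights and the fit without genes differing over 2-fold within a group were chosen after the data were seen. The intended analyses of single runs of PINT shRNA1 (first run, second run, 6 runs apart) were not run, since the table has 1 column for each RNA number, and a fit of only the groups compared gives no interaction. For LPS against control, 475 calls became 311 with the replicate block, 127 with only the groups compared, 41 with an absolute log2 fold change of at least 1 and 264 with library weights, and 293 to 412 on leaving out 1 library (295 without control replicate 2, 293 without LPS replicate 3). At that threshold PINT shRNA1 against control kept 240, PINT shRNA1 with LPS against LPS 288, PINT shRNA1 with LPS against PINT shRNA1 5 and the interaction 8. For PINT shRNA1 with LPS against PINT shRNA1 the count of 32 was 59 with median scaling, 57 with quantile normalization, 18 with no intensity trend, 17 with the block, 65 with weights and 19 to 40 on leaving out 1 library (19 and 20 without PINT shRNA1 replicates 1 and 2). The interaction gave 14 with the block. Replicate numbers are not taken to pair the samples, since residuals of 18 same-number pairs correlated at -0.0476 to 0.0569, and 0 libraries correlated best with their own number. The correlation of the hairpin-labelled differences was 0.6415 with pseudocount 0.1, 0.6194 with no filter, 0.7228 with a filter of 1, 0.593 after rescaling to a common total, 0.7862 without genes differing over 2-fold and 0.6571 to 0.6837 on leaving out 1 library. The median of LPS-raised genes in PINT shRNA1 with LPS against LPS was -0.5314 with only the groups compared and -0.7912 at the log2 threshold. With an estimated correlation 4, 0, 2, 4 and 3 lists were called in the 5 contrasts in the order of the report, and fry called 18, 20 and 4 in PINT shRNA1 against control, PINT shRNA1 with LPS against LPS, and PINT shRNA1 with LPS against PINT shRNA1. Values turned in sign for MT-ND1, PINT shRNA1 vs control, with quantile normalization (-0.07524), which sets the values of such abundant genes by rank. For EZH2, PINT shRNA1 with LPS vs LPS, not called, they were -0.03056 with median scaling, -0.002104 with quantile normalization and -0.01357 to 0.04693 on leaving out 1 library (the lowest without LPS replicate 1). For MKLN1, PINT shRNA1 with LPS vs PINT shRNA1, not called, they were -0.01938 to 0.1022 on leaving out 1 library. For IGFL1, PINT shRNA1 with LPS vs PINT shRNA1, not called, they were -0.2096 to 0.0008278 (the highest without PINT shRNA1 replicate 1). Of 177 called values of genes chosen by the naming rule, reported or not, 104 lost the call at the log2 threshold of 1, 149 in no other alternative and 17 in more than 5 others. LINC-PINT, called at 0.8142 without LPS and 0.6143 with it, is among the 104 in both. Apart from the construction of the threshold and smaller fits, the cause was not tested. Depth is known only in relative terms, so what it limits cannot be given for a gene.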

Other observations

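Both tests of explanations in this part were planned before their result was seen, and the example genes were chosen after.

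The contrasts of 3 against 3 libraries allow only 10 splits, too few for a share under 0.05. The real split gave 475 calls for LPS against control (highest other 7), 4693 for PINT shRNA1 against control (highest other 2), 5033 for PINT shRNA1 with LPS against LPS (highest other 1) and 32 for PINT shRNA1 with LPS against PINT shRNA1 (highest other 6), so that 1 of 10 splits reached the real count in each.

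Some abundant genes differed over 2-fold between libraries of one group: 258 of 6152 genes (4.19%) with a mean of at least 10 FPKM. Counting noise at low levels is argued against as the whole cause, since 2.44% of 1147 genes with a mean of at least 50 FPKM did so as well. Reads shared between overlapping annotated genes could account for part: the odds ratio of overlapping another gene on the same strand was 1.21 (0.921 to 1.58, Fisher exact p = 0.154), which does not decide it. No biological explanation was tested.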
